A study of Mus musculus with 6 samples.

How the data were processed

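The samples were 6 RNA-seq libraries of the mouse microglial line BV2, 3 wild-type controls and 3 labelled Tfam knockout. Per the labels' protocols, cells were edited with CRISPR-Cas9 and then kept in puromycin at 2 µg/mL (whether the controls were too is not clear from the labels), RNA was extracted with TRIzol, and libraries of poly(A) RNA were made with a NEBNext Ultra RNA kit, which does not mark strand. Reads of a gene and of an antisense or overlapping partner can therefore not be told apart. Per the submitters' processing notes, the tools were bcl2fastq 2.17, HISAT2 2.1.0, SAMtools 1.9 and featureCounts 2.0.0, and the genome build was GRCm39. How reads that map to several places were counted is not given in the sources used here, so values of genes with near-identical copies (Gapdh, ribosomal proteins, histones, Saa3, members of the Ifit and Slfn families and several mitochondrial genes) are uncertain. Many gene symbols in the table are older ones (Mb21d1 for cGAS, Tmem173 for STING) and are given as deposited.

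The deposited count table holds whole-number read counts per gene, not normalized by the authors, for 17872 genes, each with at least 6 counts over the 6 libraries. The authors' second table holds log2 values. From the values, each equals log2 of the count times a common total over the library total, plus 8, so that a count of 0 reads 3. The counts were used for every main result and the log2 table for 2 alternatives. Totals were 28418133, 16328037 and 14642397 counts in controls 1 to 3 and 20889786, 16511870 and 13850691 in the libraries labelled knockout. No column was left without a sample.

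Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, glmQLFit and glmQLFTest, no covariates, Benjamini-Hochberg adjustment), which kept 13403 genes and left 4469 with low counts untested. A gene was called at an adjusted p below 0.05. Standard errors are the log2 fold change over the square root of the F statistic. CPM are TMM-scaled counts per 1e+06 counts unless stated otherwise, and SDs are over the 3 libraries of a group. The 37 gene lists, the tests and most alternatives were fixed before the data were examined. Lists with at least 3 tested members (35 of 37) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, at a preset correlation of 0.01, adjusted over the lists. Of these, 18 were called, 3 with an estimated correlation, and 26 with fry. Fry tests whether a list's genes move one way on balance, without comparing them with other genes. The share of counts from mitochondrial genes was compared with an exact permutation test, which cannot go below p = 0.1.

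Genes named in the text were chosen by a rule: Tfam; the 12 largest increases and 12 largest decreases among 4668 called genes with a mean of at least 5 CPM and no overlap between the groups; and in each list up to 4 called members with the largest change and a mean of at least 1 CPM. Predicted gene models were skipped, 3 of them within the range of the largest changes. In the lists of mitochondrial mRNAs, cGAS-STING components, interferon-stimulated genes, inflammatory genes and homeostatic microglia any member could be named. In the lists of other cell types the most abundant member is also given. Where 5 or fewer members of a list moved one way, those outside the rule are named as well, and like other named genes outside the rule (Vegfa, Aldoa, Pgk1, Ldha and the mitochondrial ribosomal RNAs) they were chosen after their values were seen. Some genes the rule takes are not reported here.

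Alternatives were DESeq2 1.42.0, limma-voom, median-ratio factors, library totals only, no mitochondrial genes, no filter, a filter of 5 CPM in 3 libraries, the replicate number as a block, limma on the authors' log2 table with their added 8 replaced by 1, a test against a 1.5-fold change (glmTreat), and each library left out in turn. Offsets for transcript length and GC content, lists without transcripts under 1000 bases, and the authors' log2 table without a filter were added after the data were seen. Transcript lengths, GC content, gene order and transcript sequences came from GENCODE release M21 on GRCm38, another build than the authors', so no coordinates are given; 99.5% of tested genes had a length by symbol. Nuclear copies of mitochondrial genes were sought among its transcripts with BLAST 2.17.0 at 95% identity.

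The edgeR step was tested on simulated counts. These had the mean levels of the 3 controls and the library sizes of all 6 libraries, with 13283 genes tested. At each of 4 sizes 50 genes were changed, equally up and down, drawn from genes above a minimum count. edgeR recovered 28% of genes changed 1.25-fold and 74% of those changed 1.5-fold. It recovered 92% of those changed 2-fold and 98% of those changed 4-fold, and 7.59% of its calls were false. Far fewer genes were changed than the 5926 called in the data, so these rates may not hold for the real comparison. Replicates of a group differed by more than sampling noise in every pair (chi-square per degree of freedom from 5.33 to 15.2), so all 6 libraries were counted separately.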

Results

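RNA was sequenced from BV2 cells, an immortalised mouse microglial line, in 2 groups of 3 samples: wild-type controls and cells in which Tfam had been targeted with CRISPR-Cas9. Tfam encodes the protein that packages mitochondrial DNA and starts its transcription. The comparison asks how loss of Tfam alters the transcriptome of microglial cells. Total counts per library were 28418133, 16328037 and 14642397 in control replicates 1 to 3, and 20889786, 16511870 and 13850691 in replicates 1 to 3 of the libraries labelled Tfam knockout. Levels are given in CPM, TMM-scaled counts per 1e+06 counts, and signed numbers in brackets after gene symbols are log2 fold changes. The first principal component of log2 CPM held 67.5% of the variance and placed the 3 controls on one side and the 3 labelled knockout libraries on the other. The labels do not say whether the replicates are separate cultures, so p-values measure the spread between these samples, which may be technical.

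Tfam mRNA was not lower in the libraries labelled knockout. Its raw counts were 1098, 591 and 524 in controls and 868, 743 and 619 in the labelled knockout libraries, or 38.2 ± 1.01 and 42.3 ± 1.15 CPM (mean ± SD, n = 3 each). The log2 fold change was 0.14 ± 0.0869 (SE), with an adjusted p of 0.193 in edgeR's quasi-likelihood test. It passed as higher with library totals (0.24, adjusted p = 0.0403), with limma on the authors' log2 table (0.25, adjusted p = 0.0342, and 0.0457 unfiltered) and with offsets for transcript length and GC content (0.27, adjusted p = 0.0147). The Tfam mRNA level therefore does not show the knockout, but it could not test for an edit that leaves the mRNA in place. Each direction given here is between controls and libraries labelled knockout. Every mitochondrial DNA-encoded mRNA that could be tested fell in the libraries labelled knockout. All 12 tested mRNAs of the 13 listed passed the test, with the same count when adjusted over the list alone. Their log2 fold changes ran from -1.40 (mt-Co1) to -2.48 (mt-Nd4l), with a median of -1.89. The cytochrome b mRNA mt-Cytb fell by 2.43 ± 0.102 on the log2 scale, from 4223 ± 523 to 782 ± 3.49 CPM (adjusted p = 7.45e-12, edgeR), and the NADH dehydrogenase subunits mt-Nd1 and mt-Nd6 fell by 1.72 and 1.82. The genes of the mitochondrial genome together took 3.79% ± 0.456 of all counts in controls and 1.40% ± 0.0299 in the labelled knockout libraries (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). The list's adjusted p was 4.4e-09 with limma's camera, a call lost at adjusted p = 0.295 with an estimated correlation. Of the mRNAs tested, 9 have an annotated nuclear copy at 95% identity or more over part or all of their length, so their counts are uncertain; the other 3, mt-Nd1, mt-Nd6 and mt-Cytb, fell between 1.72 and 2.43 on the log2 scale. The 2 ribosomal RNAs, which were chosen after their values were seen, differed less. mt-Rnr2 fell by 0.88, while mt-Rnr1 was at 947 ± 116 against 791 ± 75.4 CPM, a call (adjusted p = 0.0412, edgeR) that was lost for mt-Rnr1 (without control 2 or 3 or labelled knockout 2 or 3, adjusted p up to 0.245) or with library totals, and its log2 fold change of -0.26 became 0.10 with offsets for transcript length and GC content, chosen after the data were seen.

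**Figure D1:**
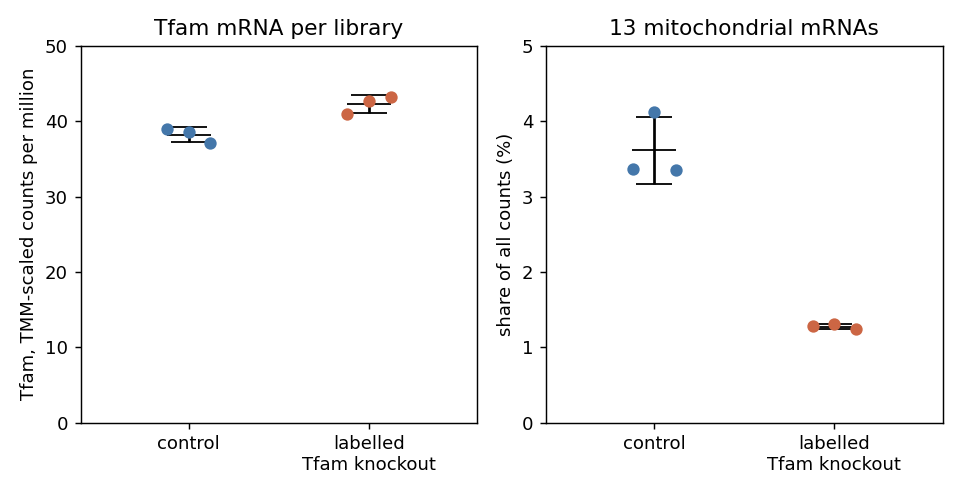
Tfam in TMM-scaled CPM (left) and the percentage of all counts from the 13 mitochondrial mRNAs (right) in each library; points are libraries, the wide bar is the group mean and the error bar 1 SD (n = 3). Tfam lies at 38.2 CPM in controls and 42.3 in the libraries labelled knockout, while the mitochondrial share goes from 3.61% to 1.27%.

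Across the transcriptome, the largest increases in the labelled knockout libraries included secreted inflammatory proteins, and the largest decreases included Arg1 and genes known to respond to low oxygen. Il6, an inflammatory cytokine, rose 47.7-fold (raw counts 15, 8 and 9 against 572, 432 and 412). Lcn2, an iron-sequestering acute-phase protein, rose 45.7-fold, and Csf3, the granulocyte colony-stimulating factor, rose 31.9-fold. Klhl3, an adaptor of a ubiquitin ligase, fell by 6.41 ± 0.259 on the log2 scale (raw counts 489, 301 and 319 against 7, 3 and 2). Arg1, the arginase associated with alternative macrophage activation, fell from 31.8 ± 3.09 to 0.64 ± 0.172 CPM. The other genes among the 12 largest increases were Adra1a (14.4-fold), the serum amyloid Saa3 (10.9-fold), Ntng2 (9.59-fold), the TNF receptor adaptor Traf1 (8.73-fold), the chemokine Cxcl2 (6.92-fold), the interferon-inducible GTPase Gbp2 (6.51-fold), Rab11fip1 (6.50-fold), the ferroxidase ceruloplasmin Cp (6.08-fold) and Id3 (5.10-fold). The other genes among the 12 largest decreases were Ankrd37 (log2 fold change -5.44), the glucose transporter Slc2a3 (-5.43), the macrophage elastase Mmp12 (-5.18), the collagen gene Col12a1 (-5.04), Plekha6 (-4.95), Serpinf1 (-4.91), the cell fusion gene Ocstamp (-4.23), Chd5 (-4.12), Selenbp1 (-4.12) and Lmcd1 (-3.90). All 24 had adjusted p-values of 5e-09 or below (edgeR), and the naming rule took them from genes whose groups did not overlap.

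Of 13403 genes tested, 5926 (44.2%) differed at an adjusted p below 0.05 in edgeR's quasi-likelihood test, 2859 higher and 3067 lower in the labelled knockout libraries. A change of at least 2-fold was seen for 398 genes that rose and 743 that fell. Tested against a change of 1.5-fold (glmTreat), 1094 genes were called. Higher genes made up 48.2% of the calls, and 61.8% of 6206 calls when libraries were scaled by their totals alone, which moved the median of all genes by 0.10 on the log2 scale. The groups did not overlap for 52.9% of tested genes, against 10% by chance. The labels do not say whether the edited cells were a clone or a pool, nor what the control cells carried, so changes that arose between the cultures for other reasons are included in these counts.

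**Figure D2:**
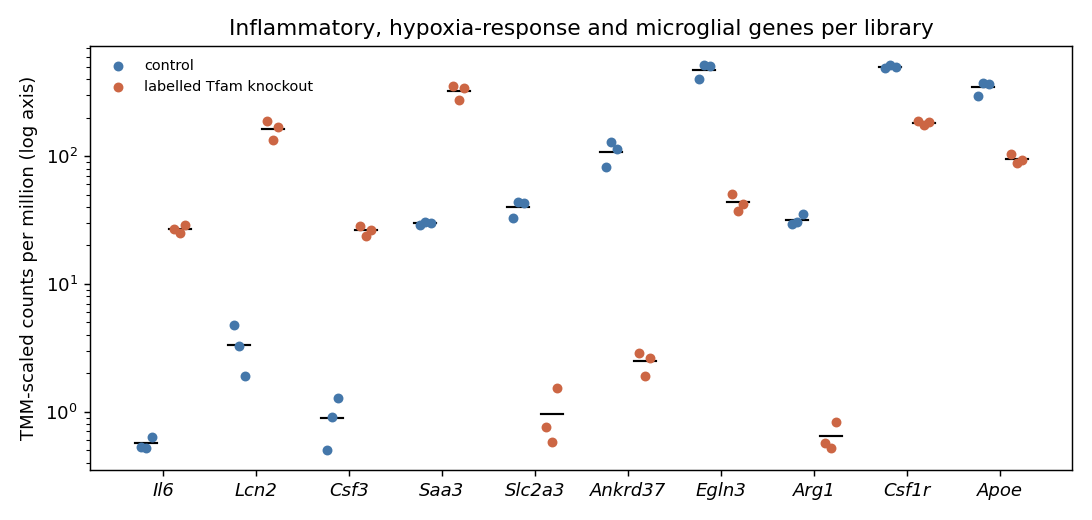
TMM-scaled CPM (log axis) of 10 genes in each control library and each library labelled Tfam knockout; points are libraries and bars are group means. Il6, Lcn2, Csf3 and Saa3 are higher, and Slc2a3, Ankrd37, Egln3, Arg1, Csf1r and Apoe are lower, in all 3 labelled knockout libraries than in any control.

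Inflammatory genes rose as a group in the labelled knockout libraries. Of 35 tested inflammatory cytokines and NF-kB targets, 30 rose and 3 fell, with a median log2 fold change of 1.05. Beside Il6, Lcn2, Csf3 and Saa3, the list held Ptgs2, the inducible cyclooxygenase (76.5 ± 4.79 to 322 ± 20.7 CPM), Il1b (3.54-fold higher) and Tnf (2.59-fold higher). The 3 that fell were the inducible nitric oxide synthase Nos2 (-0.85), the macrophage growth factor Csf1 (-0.55) and Tnfsf9 (-0.37); the call did not hold for Tnfsf9 (without labelled knockout 3, adjusted p = 0.0554). Type I interferon-stimulated genes also rose, 42 of 61, while 2 fell, Isg20 (-1.06) and Ifi27l2a (-1.02), and 17 did not pass. The antiviral gene Rsad2 rose from 38.8 ± 2.89 to 191 ± 7.64 CPM, Gbp2 rose 6.51-fold, Ifit1 rose 3.65-fold, Slfn2 rose 3.59-fold and the ubiquitin-like modifier Isg15 rose 2.84-fold. Both lists passed camera (adjusted p = 3.21e-13 for the inflammatory list and 4.4e-09 for the interferon list) and did so with an estimated correlation (adjusted p = 0.0386 and 0.0257). The list for the cGAS-STING pathway, which senses cytosolic DNA and relays to interferon, did not pass (adjusted p = 0.275, camera). Of its 16 tested genes, which are not all sensors or relays, 6 were higher and 5 lower (7 and 5 adjusted over the list alone). Among them the sensor cGAS, listed under its older symbol Mb21d1, rose 1.94-fold (29.2 ± 3.68 to 57.2 ± 2.1 CPM), the kinase Ikbke rose 2.88-fold, Trim56 rose 2.03-fold and Irf7 rose 1.54-fold. The 5 lower genes were the adaptor STING, listed as Tmem173 (-0.50), the transcription factor Irf3 (-0.45), Samhd1 (-0.33), Ddx41 (-0.24) and Aim2 (-0.20); calls did not hold for Ddx41 (without control 2 or labelled knockout 2 or 3, adjusted p up to 0.0863) and Aim2 (without control 1 or 3 or labelled knockout 1 or 3, adjusted p up to 0.186) or, for both, with library totals, nor for Aim2 without a filter on low counts. Counts in the inflammatory and interferon lists were the same when adjusted over the list alone.

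Genes of the hypoxia response and of glycolysis fell together in the labelled knockout libraries. Of 27 hypoxia-response genes tested, 22 fell, 2 rose and 3 did not pass, with a median log2 fold change of -1.42. Ankrd37 fell from 108 ± 24.3 to 2.48 ± 0.515 CPM, Selenbp1 from 539 ± 89 to 31 ± 1.8 CPM, the prolyl hydroxylase Egln3 from 475 ± 65.4 to 43.4 ± 6.59 CPM and the mitophagy receptor Bnip3 from 124 ± 9.96 to 13.4 ± 1.27 CPM. Vegfa, the vascular growth factor, did not pass (223 ± 6 against 234 ± 6.12 CPM). The 2 that rose were Pfkfb3 (0.53) and Car12 (0.29), and the call did not hold for Car12 (without control 2 or labelled knockout 2, adjusted p up to 0.0565). Of 23 genes of glycolysis and lactate export, 21 fell and 2 rose, Pfkfb3 and the lactate transporter Slc16a1 (0.43), with a median of -1.04. The glucose transporter Slc2a1 fell from 180 ± 7.23 to 67.8 ± 15.7 CPM, with Slc2a3 (-5.43), Pdk1 (-1.42) and Gpi1 (-1.41). The enzymes Aldoa (-1.27), Pgk1 (-1.04) and Ldha (-0.86) fell too, and the lists share 6 genes. Both lists passed camera (adjusted p = 9.83e-10 for hypoxia and 9.54e-10 for glycolysis), calls lost with an estimated correlation (adjusted p = 0.199 and 0.295). Vegfa, Pfkfb3, Car12, Slc16a1, Aldoa, Pgk1 and Ldha were chosen after their values were seen, and the counts were the same when adjusted over the list alone.

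Genes of other metabolic groups were called in both directions. As 44.2% of all tested genes were called, a count near that share does not set a list apart. Among pentose phosphate and nucleotide synthesis genes, 18 of 27 rose and 4 fell (19 and 4 adjusted over the list alone), with a median of 0.29. The phosphoribosyl pyrophosphate synthetase Prps1 rose 1.96-fold, the ribonucleotide reductase subunit Rrm2 rose 1.79-fold, Ctps rose 1.72-fold and Tyms rose 1.59-fold, while Pgls (-0.57), Pgd (-0.28), Prps2 (-0.22) and Tkt (-0.22) fell. The list passed camera (adjusted p = 0.00162), a call lost at adjusted p = 0.478 with an estimated correlation. Its members Rrm1, Rrm2 and Tyms are also in the DNA replication and S phase list, so the lists are not independent. In the tricarboxylic acid cycle list, 7 of 25 rose and 6 fell (adjusted p = 0.93, camera). Acod1, which makes itaconate and is also in the inflammatory list, rose 4.05-fold. The malic enzyme Me1 fell by 1.44 on the log2 scale, Mdh1 fell by 0.57 and the pyruvate carrier subunit Mpc1 rose 1.45-fold. Fatty acid oxidation genes included 4 of 23 that rose, the acyl-CoA synthetases Acsl5 (1.12), Acsl1 (0.49), Acsl3 (0.39) and Acsl4 (0.24), and 8 that fell, among them Acaa2 (-1.23), Acadm (-0.70) and Acat1 (-0.59) (5 and 9 adjusted over the list alone; adjusted p = 0.318 for the list). Fatty acid and lipid droplet genes included 5 of 25 that rose, Dgat2 (0.81), Cd36 (0.43), Acaca (0.34), Elovl1 (0.34) and Hilpda (0.32), and 11 that fell, with Scd2 (-1.17), Lpl (-0.83) and Abcg1 (-0.69) (adjusted p = 0.141). In cholesterol biosynthesis, 5 of 22 rose, Lss (0.79), Idi1 (0.49), Hsd17b7 (0.48), Insig1 (0.46) and Srebf2 (0.20), and 5 fell, among them Nsdhl (-0.71), Sqle (-0.29), Dhcr7 (-0.24) and Msmo1 (-0.23); the adjusted p was 0.745, and the median (-0.04) and mean (0.02) differed in sign. Calls did not hold for Prps2 (without control 1 or 2 or labelled knockout 3, adjusted p up to 0.161), Tkt (without control 1, 2 or 3 or labelled knockout 2 or 3, adjusted p up to 0.0985), Acsl4 (without control 2 or 3 or labelled knockout 2 or 3, adjusted p up to 0.0822), Hilpda (without control 1 or labelled knockout 3, adjusted p up to 0.12), Srebf2 (without control 2 or labelled knockout 3, adjusted p up to 0.0764), Dhcr7 (without control 1, 2 or 3 or labelled knockout 1 or 3, adjusted p up to 0.166) and Msmo1 (without control 2 or 3 or labelled knockout 3, adjusted p up to 0.209). With library totals Pgd, Prps2, Tkt, Dhcr7 and Msmo1 did not pass, nor did Dhcr7 with DESeq2 or Sqle with the authors' log2 table unfiltered. Without control 3, 4 tricarboxylic acid cycle genes were higher, and with library totals 8 lipid droplet genes were. Counts in the tricarboxylic acid, lipid droplet and cholesterol lists were the same when adjusted over the list alone.

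Tested genes listed as homeostatic or disease-associated in microglia mostly fell in the labelled knockout libraries. Of 44 symbols in the homeostatic list, only 26 could be tested. Of these 26, 20 fell and 6 did not pass, with a median log2 fold change of -0.57. The adhesion receptor Adgrg1 fell from 27.9 ± 3.66 to 5.69 ± 0.344 CPM, the colony-stimulating factor receptor Csf1r from 501 ± 12.8 to 182 ± 6.25 CPM, and the list also held Rhob (-1.54) and Jun (-1.19). The lipid receptor Trem2 (-0.83) and its signalling partner Tyrobp (-0.83) fell as well. Of 35 disease-associated microglia genes, 21 fell and 5 rose, with a median of -0.54. Mamdc2 fell from 76.7 ± 5.01 to 9.2 ± 1.26 CPM, the lipoprotein Apoe from 347 ± 44 to 95 ± 7.29 CPM, and the integrin Itgax (-1.46) and the lectin Cd22 (-1.39) fell, while Gpr65 (1.38), Fth1 (0.68), Ctsd (0.41), Gpnmb (0.28) and Ctsb (0.23) rose. Lysosome genes included 24 of 55 that fell, with Ctsf (-1.13), Atp6v0d2 (-1.07), Glb1 (-0.85) and Ctsa (-0.79), and 5 that rose, Ctsd, Ctsb, Idua (0.51), Atp6v0b (0.33) and Lamp1 (0.29). These 3 lists passed camera (adjusted p = 8.99e-08, 0.000351 and 0.0041), calls lost with an estimated correlation (adjusted p = 0.169, 0.311 and 0.441). Phagocytic receptors were 9 higher and 17 lower of 28 (adjusted p = 0.0866), among them Itgax, Colec12 (-1.27), the lipopolysaccharide co-receptor Cd14 (1.13) and the inhibitory Fc receptor Fcgr2b (-1.11). Of MHC class I presentation genes, 5 of 16 rose, Tap1 (0.71), Erap1 (0.60), Psmb8 (0.52), Psme2 (0.46) and Tapbp (0.40), and 3 fell, Calr (-0.39), Psme1 (-0.30) and H2-K1 (-0.26) (6 and 4 adjusted over the list alone; adjusted p = 0.198). Of MHC class II presentation genes, 2 of 8 rose, Cd86 (0.62) and Cd80 (0.28), and 5 fell, Lgmn (-0.52), Cd74 (-0.39), Ifi30 (-0.38), H2-DMb1 (-0.38) and Ctss (-0.25) (adjusted p = 0.316). Calls did not hold for Gpr65 (without control 1 or labelled knockout 2, adjusted p up to 0.0882), Gpnmb (without control 3 or labelled knockout 3, adjusted p up to 0.097), Ctsb (without control 3 or labelled knockout 1 or 3, adjusted p up to 0.155), Lamp1 (without control 3, adjusted p = 0.0558), Psme1 (without control 2, adjusted p = 0.11), H2-K1 (without control 2 or 3 or labelled knockout 2 or 3, adjusted p up to 0.128), H2-DMb1 (without control 2 or 3 or labelled knockout 2, adjusted p up to 0.157), Ctss (without control 2 or 3 or labelled knockout 2 or 3, adjusted p up to 0.187) and Cd80 (without control 1 or 3 or labelled knockout 1 or 3, adjusted p up to 0.0709). With library totals Psme1, H2-K1, H2-DMb1 and Ctss did not pass, nor did Ctsb and Psme1 with offsets for transcript length and GC content. Without control 2, 15 lysosome genes were lower, while with library totals 8 lysosome and 9 class I genes were higher, the latter also 9 with the offsets. Counts other than those of the class I list were the same when adjusted over the list alone.

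Cell cycle genes rose in the labelled knockout libraries. Of 43 mitosis genes, 40 rose and 3 did not pass, with a median log2 fold change of 0.70, and the count was the same when adjusted over the list alone. Gtse1 rose 2.52-fold, cyclin A2 (Ccna2) rose from 27.1 ± 1.14 to 62.5 ± 3.31 CPM, Ckap2l rose 2.18-fold and the kinase Aurka rose 1.99-fold. The list passed camera (adjusted p = 2.22e-16) and did so with an estimated correlation (adjusted p = 0.0257). Of 48 DNA replication and S phase genes, 34 rose and 14 did not pass (36 and 1 adjusted over the list alone), with a median of 0.47. Mcm10 rose 2.21-fold, Pole rose 1.91-fold and Exo1 rose 1.85-fold. Without labelled knockout 1, 32 rose and 3 fell (Ccne1, Rfc2 and Slbp, chosen after their values were seen). That list passed camera (adjusted p = 8.71e-09), but not with an estimated correlation (adjusted p = 0.311).

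Stress-response genes rose in part. Of 41 integrated stress response genes, targets of the transcription factor ATF4, 21 rose and 7 fell, with a median of 0.23. The stress cytokine Gdf15 rose from 80.3 ± 3.19 to 295 ± 13.6 CPM, the cystine transporter Slc7a11 rose 3.6-fold, and the transcription factor Ddit3 rose 2.79-fold. Ero1l, an oxidase that is also in the hypoxia list, fell by 1.70 on the log2 scale. Endoplasmic reticulum stress genes were 13 higher and 4 lower of 29 (14 and 6 adjusted over the list alone), with Ddit3 and the chaperones Hspa5 (0.87) and Hsp90b1 (0.75) higher and Sec61b (-0.79), Calr (-0.39), Edem1 (-0.32) and Sdf2l1 (-0.29) lower. Both passed camera (adjusted p = 0.0013 and 0.0324), calls lost with an estimated correlation (adjusted p = 0.478 and 0.311). The second was also lost without control replicate 1 (adjusted p = 0.0626), without labelled knockout replicate 3 (0.0539), with a filter of 5 CPM (0.0526), with the offsets (0.0736) and without short transcripts (0.0721). Its median log2 fold change was 0.17, against 0.19 with the offsets and 0.17 over the 27 members of at least 1000 bases, and the call of 1 member did not hold for Sdf2l1 (without control 2 or 3 or labelled knockout 2 or 3, adjusted p up to 0.257) or with library totals, limma-voom or the offsets. Autophagy and mitophagy genes were 6 higher and 16 lower of 34 (adjusted p = 0.0866), with Bnip3 (-3.21), the selective autophagy receptor Sqstm1 (1.78), Bnip3l (-1.04) and Wipi1 (-1.02). NRF2 antioxidant genes were 12 higher and 11 lower of 34 (13 and 13 adjusted over the list alone; adjusted p = 0.889), with Slc7a11, Me1, the haem oxygenase Hmox1 (-1.40) and Gstm1 (-1.16). In the list of p53 targets and senescence genes, 10 of 30 rose and 7 fell, with Gdf15, Gadd45a (1.76) and Fas (1.46) among the higher. That list did not pass (adjusted p = 0.926), and its median (-0.09) and mean (0.01) differed in sign. Without control 3, 3 autophagy genes were higher, and with library totals 10 were lower. Counts in the ATF4, autophagy and p53 lists were the same when adjusted over the list alone.

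Nuclear genes that act in mitochondria beside the respiratory chain were called in both directions. Calls made up 44.2% of all tested genes, so the counts below do not by themselves set these lists apart. Of 32 genes of mitochondrial DNA maintenance and transcription, 11 rose, with the pyrimidine carrier Slc25a33 (0.65) and Mgme1 (0.58) and Tfb1m (0.58), and 4 fell, the single-strand binding protein Ssbp1 (-0.76) and Endog (-0.57), Slc25a36 (-0.53) and Tk2 (-0.37) (adjusted p = 0.198, camera). Mitochondrial proteases and chaperones were 5 higher of 20, Hspd1 (0.50), Hspa9 (0.49), Lonp1 (0.41), Dnaja3 (0.36) and Clpp (0.27), and 5 lower, Afg3l2 (-0.66), Clpx (-0.58), Phb (-0.50), Timm17a (-0.30) and Grpel1 (-0.21) (adjusted p = 0.889). Calls did not hold for Clpp (without labelled knockout 3, adjusted p = 0.0532) and Grpel1 (without control 2 or 3 or labelled knockout 2 or 3, adjusted p up to 0.232) or, for Timm17a and Grpel1, with library totals, nor for Grpel1 with DESeq2 or limma-voom. Proteins of the mitochondrial ribosome were 10 higher and 19 lower of 72 (adjusted p = 0.656), with Mrps21 (-1.52), Mrps18a (0.98), Mrpl51 (-0.87) and Mrpl18 (-0.62). With library totals 22 mitochondrial ribosome genes were higher and 12 lower, 18 were higher with the offsets, and 8 proteases and chaperones were higher with library totals. Counts in these 3 lists were the same when adjusted over the list alone.

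**Figure D3:**
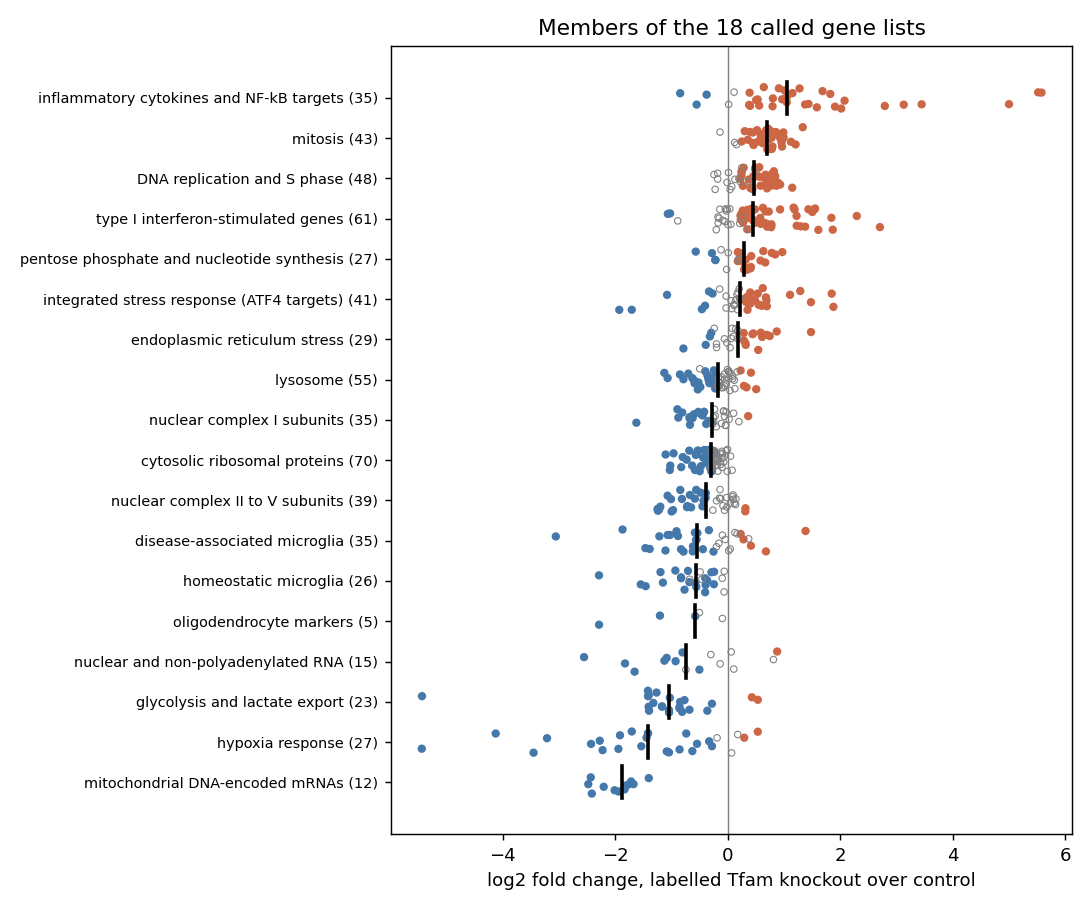
Log2 fold changes (labelled Tfam knockout over control) of the tested members of the 18 lists called by camera with a preset correlation of 0.01; filled points passed edgeR's test (orange higher, blue lower), open points did not, black bars are medians and the number of members is in brackets. The medians run from -1.89 for mitochondrial mRNAs to 1.05 for inflammatory genes.

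Some nuclear genes for the respiratory chain and for ribosomal proteins were lower, and so were short transcripts across the transcriptome. Of 35 nuclear complex I subunits, 18 fell and 1 rose (Ndufs1 (0.36)), with a median of -0.28, and Ndufv3 (-1.62), Ndufa1 (-0.89), Ndufb3 (-0.88) and Ndufa3 (-0.81) fell. Of 39 nuclear subunits of complexes II to V, 21 fell and 2 rose (Cyc1 (0.32) and Atp5b (0.31)), with a median of -0.39, and Atp5j2 was 2.38-fold, Uqcrh 2.36-fold and Cox7b 2.33-fold lower. Of 70 cytosolic ribosomal proteins, 38 fell and 32 did not pass (0 and 43 adjusted over the list alone), with a median of -0.29, led by Rpl38 (-1.10), Rpl39 (-1.03), Rpl37a (-1.02) and Rps28 (-0.96). Control 1 stood apart from the other controls. Ribosomal proteins took 7.01% of its counts against 8.58% and 8.14% in controls 2 and 3, and 7.70%, 6.45% and 7.22% in the labelled knockout libraries (exact two-sided permutation p = 0.3). Rpl38 was at 151, 381 and 345 CPM in controls 1 to 3, and Rps28 overlapped between the groups (219 CPM in control 1 against 228 and 242 in labelled knockout 1 and 3). The number of ribosomal proteins that fell was 52 without control 1, 18 without control 2, 21 without control 3 and 21 without labelled knockout 2. The 3 lists passed camera (adjusted p = 0.00432, 0.00524 and 7.92e-05) and were lost with an estimated correlation (adjusted p = 0.652 for each) and with fry (adjusted p = 0.132, 0.116 and 0.19). The median log2 fold change was -0.27 over 426 genes with transcripts under 500 bases and 0.06 over 2992 genes of 4000 bases or more. Without members shorter than 1000 bases, an alternative chosen after the data were seen, the medians of the respiratory-chain lists were -0.07 over 11 complex I genes and 0.02 over 16 others, and neither list passed camera (adjusted p = 0.552 and 0.892). Both were also lost without labelled knockout replicate 2 (adjusted p = 0.0601 and 0.0609), and the ribosomal protein median over 17 genes of at least 1000 bases was -0.30. With offsets for transcript length and GC content the medians were -0.16 for complex I, -0.17 for complexes II to V and -0.12 for ribosomal proteins, and the call of complex I was lost (adjusted p = 0.0548). Of complex I, 3 genes were higher with the offsets and with library totals (Ndufs1, Ndufb8 and Ndufv1, chosen after their values were seen), and of complexes II to V 6 were. Counts in the respiratory-chain lists were the same when adjusted over the list alone.

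**Figure D4:**
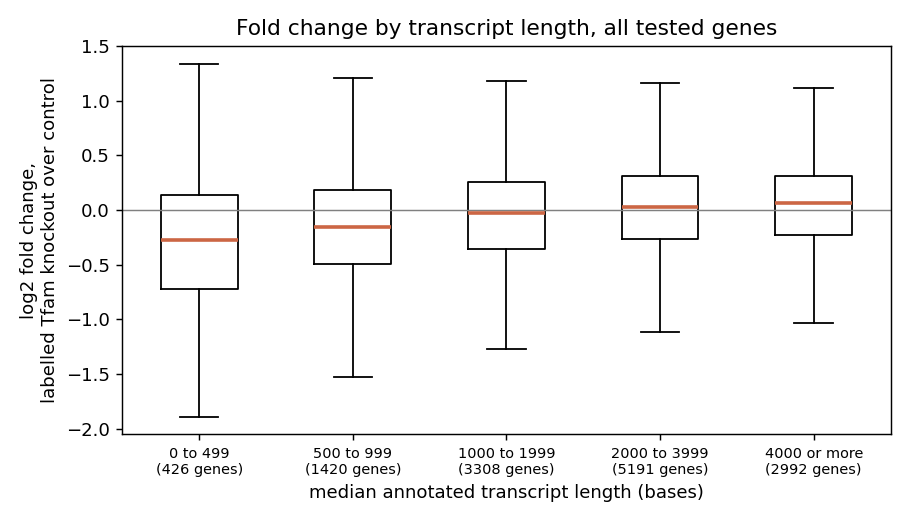
Log2 fold change (labelled Tfam knockout over control) of all tested genes with an annotated length, by median annotated transcript length in bases; boxes span the quartiles, the orange line is the median and whiskers reach at most 1.5 times the box height, with points beyond them not drawn. The median goes from -0.27 in the shortest class to 0.06 in the longest.

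Nuclear and non-polyadenylated RNAs, listed as a check of RNA quality, were 1 higher (Terc (0.88)) and 8 lower of 15, with Hist1h4c (-2.55), Hist1h4d (-1.82), Hist1h1d (-1.65) and Hist1h2bc (-1.13). The lower genes named here are histone genes, and whether RNA selection or the cells themselves differed was not tested. The list's adjusted p was 0.0229 with camera but adjusted p = 0.356 with an estimated correlation and 0.0548 with the length and GC offsets (median log2 fold change -0.74, and -0.55 with them), with 4 lower of the 5 that a filter of 5 CPM left, and the call did not hold for Terc (without control 2 or labelled knockout 2 or 3, adjusted p up to 0.0706). Called markers of other cell types fell, apart from Lck and 3 macrophage markers, which rose. As BV2 is a single cell line, these levels need not come from other cells. Scaled by library totals, the most abundant neuron marker Camk2a was at 35.7 ± 2.12 and 23.5 ± 1.56 CPM in controls and labelled knockout libraries, the astrocyte marker Aldoc, which is also a glycolytic enzyme, at 205 ± 14.3 and 83 ± 4.51, and the oligodendrocyte marker Cnp at 38.3 ± 0.261 and 27.4 ± 3.6. The endothelial marker Flt1 was at 173 ± 7.58 and 76.5 ± 2.44, the macrophage marker Lyz2 at 940 ± 29.9 and 693 ± 72, and the lymphocyte marker Lck at 4.45 ± 0.673 and 8.1 ± 0.919. Oligodendrocyte markers passed camera (3 of 5 lower, Pdgfra (-2.29), Mbp (-1.20) and Cnp (-0.58); adjusted p = 0.0263) but not with an estimated correlation (adjusted p = 0.295) or without a filter on low counts (0.131). Neuron markers (2 of 4 lower, Syn1 (-1.17) and Camk2a (-0.70)) had an adjusted p of 0.127, and fibroblast and endothelial markers (4 of 8 lower, Pdgfrb (-1.98), Flt1 (-1.28), Kdr (-1.15) and Vwf (-1.01)) one of 0.0866. Peripheral macrophage markers were 3 higher of 14, Clec4e (2.00), Clec4d (0.47) and Hp (0.38), and 7 lower, among them F10 (-2.78), S100a8 (-2.35) and Cbr2 (-1.68) (adjusted p = 0.112). Calls did not hold for Pdgfrb (without labelled knockout 1 or 2, adjusted p up to 0.0655) and Hp (without control 3 or labelled knockout 1, adjusted p up to 0.0674). Astrocyte and lymphocyte markers had too few tested members for a list test, and 1 of 2 astrocyte markers (Aldoc (-1.40)) fell while the 1 lymphocyte marker tested (Lck (0.76)) rose. Counts in these lists were the same when adjusted over the list alone.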

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

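The offsets for transcript length and GC content, the lists without transcripts under 1000 bases and the authors' log2 table without a filter were chosen after the data were seen; the other alternatives were planned. The 5926 calls became 5554 with DESeq2, 5873 with limma-voom, 5934 with median-ratio factors, 6206 with library totals, 5959 without mitochondrial genes, 5850 with no filter, 5301 with a 5 CPM filter, 6207 with the authors' log2 table, 6225 with that table unfiltered, 6399 with the offsets and 4847 to 5743 with each library left out. Genes called under both kept their sign, except 1 with the offsets. The labels do not say whether same-numbered samples were paired. Deviations of same-numbered samples correlated at -0.104, -0.114 and 0.0395, and only control 3 and labelled knockout 3 correlated best with their own number. With 3 libraries per group, these correlations show no clear pairing but cannot exclude a weak one. A replicate block gave 5255 calls and changed no list call. The block did end calls of named genes, among them mt-Rnr1, Aim2, Grpel1, Ctsb, Gpnmb, Dhcr7, Ctss and Tkt (adjusted p up to 0.124, edgeR). A test against a 1.5-fold change, stricter by construction, called 1094 genes, 389 higher and 705 lower, with 258 higher at least 2-fold. The 5 CPM filter, which tested 10075 genes, called 209 higher and 400 lower at least 2-fold. Over 253 single genes and all alternatives, 4243 values kept their direction and side of the threshold, 267 lost the call, 11 gained it and 9 changed sign. Sign changes were Ifi205 with totals (0.0077) and with 1 library left out (-0.31 to 0.093, higher without control replicate 2 or labelled knockout replicate 2), Ifi207 with totals (0.027) and with the authors' table, filtered or not (0.025 each), Ifi204 with 1 library left out (-0.012 to 0.081, lower without labelled knockout replicate 1) and with the offsets (-0.0060), and mt-Rnr1 with the offsets (0.098). Tfam had a log2 fold change of 0.24 (adjusted p = 0.0403) with totals, 0.25 (adjusted p = 0.0342) with the authors' table, 0.25 (adjusted p = 0.0457) with that table unfiltered and 0.27 (adjusted p = 0.0147) with the offsets, and did not pass elsewhere (log2 fold change from 0.13 to 0.17 with 1 library left out). The mitochondrial share differed by -2.52 to -2.12 percentage points with 1 library left out. At this depth 4469 genes had too few counts to be tested. The cause of each change in a list call was not tested, apart from the removal of short transcripts.

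With an estimated correlation 3 lists were called in place of 18. Adjusted p-values became 0.295 (mitochondrial mRNAs, glycolysis, oligodendrocyte markers), 0.652 (complex I, complexes II to V, ribosomal proteins), 0.478 (ATF4 targets, pentose phosphate), 0.311 (disease-associated microglia, endoplasmic reticulum stress, S phase), 0.169 (homeostatic microglia), 0.441 (lysosome), 0.199 (hypoxia) and 0.356 (nuclear RNA). With fry, complex I (0.132), complexes II to V (0.116) and ribosomal proteins (0.19) were lost. Fry gained mitochondrial DNA maintenance, p53 targets and macrophage markers (0.0166 each), fatty acid oxidation (0.0116), lipid droplet (5.69e-05), cGAS-STING and autophagy (0.000518 each), MHC class I (0.0163), phagocytic receptors (0.000333), and neuron and endothelial markers (0.000777 each). The offsets ended complex I and nuclear RNA (0.0548 each) and endoplasmic reticulum stress (0.0736). Without short transcripts, complex I (0.552), complexes II to V (0.892) and endoplasmic reticulum stress (0.0721) were lost. Totals gained phagocytic receptors (0.0354), macrophage and endothelial markers (0.0379 each). No filter gained phagocytic receptors (0.0234) and lost oligodendrocyte markers (0.131), and the 5 CPM filter lost endoplasmic reticulum stress (0.0526) and gained endothelial markers (0.00334). With 1 library left out, adjusted p ran over 1.69e-05 to 0.0601 for complex I and 4.52e-05 to 0.0609 for complexes II to V (both lost without labelled knockout replicate 2) and 0.0238 to 0.0626 for endoplasmic reticulum stress (lost without control 1 or labelled knockout 3). It ran over 0.0436 to 0.0677 for phagocytic receptors and 0.0396 to 0.0855 for macrophage markers (gained without labelled knockout 1), 0.023 to 0.185 for neuron markers (gained without control 3) and 0.0384 to 0.163 for endothelial markers (gained without control 3 or labelled knockout 2). Lists not called by camera changed direction in settings that did not call them either: the mitochondrial ribosome with the offsets (0.796) and without control 2 or labelled knockout 2 (0.163 to 0.988 over the libraries left out), proteases and chaperones with fry (0.924), without short transcripts (0.892) and without labelled knockout 1 (0.644 to 0.971), the tricarboxylic acid cycle with totals (0.944), fry (0.337) and without control 1 or labelled knockout 2 (0.776 to 0.99), NRF2 with the 5 CPM filter (0.986), without short transcripts (0.935) and without labelled knockout 1 (0.647 to 0.99), and p53 targets with the 5 CPM filter (0.981), the offsets (0.943) and without short transcripts (0.892).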

Other observations

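The gene families in the next paragraph, and the tests on the hypoxia and glycolysis lists and on the Tfam label, were chosen after their values were seen; the tests on the number of calls were set before their results were seen.

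Genes of the NF-kappaB system itself also rose. Nfkb1, Nfkb2, Relb, Nfkbia, Nfkbiz and Tnfaip3 are in the inflammatory list as well, so this is not a separate result for them. Of 12 subunits and inhibitors tested, 11 rose, with a median log2 fold change of 1.05, among them the inhibitors Nfkbia (1.91) and Nfkbie (1.35) and the subunit Nfkb1 (1.28), while Rela (0.10) did not pass (edgeR). All 7 calcium-binding S100a genes tested fell, with a median of -1.87; S100a6 fell from 561 ± 140 to 131 ± 22.8 CPM, and S100a11 (-1.87), S100a1 (-1.49) and S100a13 (-1.45) fell too. In the Schlafen family 4 of 6 rose, Slfn2, Slfn3 (2.47-fold), Slfn8 and Slfn9, of which all but Slfn3 are also in the interferon list. Among annexins 6 of 10 fell, with Anxa2 falling from 913 ± 84.3 to 314 ± 27.4 CPM. Histone genes, whose mRNAs mostly lack a poly(A) tail, were 30 lower and 1 higher (Hist2h3c2 (0.79)) of 37, with Hist1h2ac (-2.26) and Hist1h2bg (-1.94), and near-identical copies make their counts uncertain; with library totals 27 were lower. The median of each family kept its sign with library totals, median-ratio factors and the offsets. Calls did not hold for Hist2h3c2 (without control 3 or labelled knockout 1, adjusted p up to 0.0817).

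The number of called genes was weighed against technical explanations. With the offsets for transcript length and GC content 6399 genes were called, 5490 of them among the 5926, which argues against that trend as the source of most calls. Only 0.816% of called genes with a position (48 of 5879) lay in runs of 51 neighbouring genes shifted by more than 0.3 on the log2 scale. This argues against copy-number differences that shift runs by more than 0.3 as the source of most calls. Smaller shifts were not counted, and runs on chromosomes 7 (-0.295) and 19 (0.287) came close. Of these 48 genes, 31 are on chromosome 13, where the lowest run median was -0.857. That shift was local, as the median over all 551 placed genes of chromosome 13 was -0.0673 from that of all genes. The source of that run, including whether the lower histone genes above lie in it, was not tested. The real split, with 5926 calls, was the only 1 of the 10 splits of the 6 libraries to reach that number, against a highest other of 0 (edgeR; 81 to 507 genes at an unadjusted p below 0.05, and at most 1 with DESeq2), and 10 splits are too few for a share under 0.05. Each other split mixes controls with labelled knockout libraries, so the difference between the groups adds to the spread within each side. Their low counts therefore do not measure how many of the calls are false. Differences between cultures or clones that are unrelated to Tfam remain open, since the labels do not say how the cells were derived.

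Tfam mRNA was not lower in the libraries labelled knockout (log2 fold change 0.14, and 0.24 to 0.27 in the settings that called it higher). As Tfam is needed to transcribe mitochondrial DNA, labels exchanged between the groups would put the lower mitochondrial mRNA share in the controls, but that share was 2.83-fold higher in controls, which argues against an exchange. A small edit that leaves the mRNA in place while ending the protein may be a candidate explanation, and the fold change of 1.10 in Tfam counts does not decide it, since gene counts show neither the edit nor the protein.

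The lower hypoxia and glycolysis genes were weighed as a set of 44 genes, 38 lower and 3 higher. Their median log2 fold change was -1.12 and, with the offsets, -1.06, which argues against a length or GC trend as the source. Control cultures that were denser or at a later stage could show more hypoxia and less mitosis, and the mitosis list was higher in the labelled knockout libraries (median log2 fold change 0.70), in all 3 against all 3 controls. Less use of oxygen by cells with fewer mitochondrial mRNAs, whose share was 2.83-fold higher in controls, may be another. These explanations cannot be told apart, as culture density and oxygen were not recorded in the labels and each would go with the groups.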
